A study of Homo sapiens with 6 samples.

How the data were processed

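Total RNA of SY5Y neuroblastoma cells was extracted with Trizol and made into libraries with a NEBNext Ultra kit, per the labels' protocols. The strand setting of the counting is not given in the sources used here, so reads of overlapping genes on opposite strands were not told apart. The deposited gene counts are whole numbers per gene and library. HISAT2 2.0.5 and featureCounts 1.5.0-p3 are named in the submitters' processing notes, without their settings. Those notes name hg19 as the genome build. All 58735 genes of the count table nevertheless have the identifiers, starts and ends of GENCODE release 29 on GRCh38, and coordinates are therefore given as GRCh38. The deposited FPKM values, made by the authors, equal the counts divided by the gene length in the file and by a scaled library total that lay between 0.968 and 1.03 times the sum of the counts, so they hold the same reads as the counts and are not independent of them.

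Samples were grouped by their labels into 3 libraries with DLX5 overexpression and 3 controls, and no library was left out. The total counts per library ran from 14644077 to 16886026. The counts of libraries of one group differed by 2.23 to 5.07 times the sampling noise (chi-square over its degrees of freedom), so no library was taken for a copy of another. Between groups this ratio was 96.7 to 107.

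Counts were analysed with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr with the group as design, which left 17269 of the 33755 genes with any count. Library sizes were scaled by TMM, and the groups were compared with the two-sided quasi-likelihood test and Benjamini-Hochberg adjustment over all tested genes, with no covariate. A gene passed at an adjusted p under 0.05. The biological coefficient of variation was 6.17%. CPM values are scaled by TMM, and ± after a CPM is the SD over 3 libraries. After a log2 fold change, ± is a standard error. It was computed as the size of the change over the square root of the F statistic of the quasi-likelihood test. Where a large change leaves few counts in a group, it can be smaller than the counting error. A fold against a group with 0 counts was computed against a floor of 3 counts over the group, and for groups with 1 to 3 counts the ratio is given with an exact 95% binomial counting interval. A design with 3 libraries against 3 cannot give an exact permutation p under 0.1, so p-values rest on the model.

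Gene lists, 34 in number with 760 distinct genes, were written from textbook knowledge before the data were examined, as were the groups, the tests, the other settings to try and the rule for named genes. DLX5 was left out of every list. Lists were tested with camera (limma 3.58.1, preset correlation 0.01, two-sided) and adjusted over the 34 lists. The rule named DLX5 and MYCN, the 12 protein-coding genes with the largest rise and the 12 with the largest fall among those that passed, did not overlap between groups and had at least 2 log2 CPM on average, and up to 4 members of each list with the smallest adjusted p. Other genes are said to be chosen after their values were seen. Of the 174 genes so named, 108 overlap another gene of the annotation, and for 30 of them an overlapping gene holds over 10% as many counts. For 10 of the 174 an overlapping gene holds at least as many counts. A few of the 174 are not reported here.

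The test was checked on simulated counts with the control means and the library sizes of these libraries. Of 16524 simulated genes tested, it recovered 30.6% of 49 genes changed by 1.25-fold, 57.4% of 47 changed by 1.5-fold, 91.3% of 46 changed by 2-fold and 100% of 49 changed by 4-fold, and it called 18 of 16333 unchanged genes. Far fewer genes were changed in the simulation than the 10121 of 17269 called in the data. Adjustment was therefore stricter there, and the recovery rates need not hold for the data.

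The alternatives were RLE and upper-quartile factors, DESeq2 1.42.0, limma-voom, no filter on low counts, a filter of 1 CPM in 3 libraries, protein-coding genes only, the replicate number as a block, limma on log2(FPKM + 1) and log2(FPKM + 0.1), an adjusted p under 0.01, a minimum change of 2-fold, each library left out, and for the lists an estimated correlation and fry. Library totals with no scaling factors and a test against a 1.5-fold change were added after the data were seen. GC content and gene length were taken from GENCODE 29, and their trend over all genes was removed with a loess fit of span 0.3. Figures were drawn with matplotlib 3.10.9.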

Results

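RNA was sequenced from SY5Y cells, a human neuroblastoma line, in 6 libraries. In 3 of them the cells overexpressed DLX5, a homeobox transcription factor of the distal-less family, and 3 were controls. The comparison bears on how DLX5 relates to MYCN, the MYC family transcription factor that is amplified in part of neuroblastomas, and on what DLX5 does to the rest of the transcriptome. Each library had between 14644077 and 16886026 reads assigned to genes. The labels do not say whether the replicates came from separate cultures, so p-values measure only the spread between these libraries, which may be technical. Reads of the mitochondrial chromosome made up 8.21% ± 0.795 of the DLX5 libraries and 7.48% ± 0.404 of the controls (SD, n = 3).

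DLX5 itself (ENSG00000105880, chromosome 7, 97020392 to 97024950, minus strand, GRCh38) stood at 1609 ± 59.1 CPM (counts scaled to the normalised library size) in the DLX5 libraries and 12.8 ± 0.804 CPM in the controls (SD, n = 3). That is a log2 fold change of 6.97 with a standard error of 0.08, or 125-fold (edgeR quasi-likelihood test, adjusted p = 1.86e-28). The 3 DLX5 libraries held 1582, 1569 and 1677 CPM, and the 3 controls 12.4, 12.35 and 13.76 CPM, so each library matched its label. The gene counts do not separate reads of an introduced copy from reads of the cells' own gene. The other DLX genes that could be tested also rose. DLX6, the neighbour of DLX5, rose by 0.49 ± 0.10 (log2 fold change ± SE) and DLX4 by 2.29 ± 0.51. DLX6-AS1, which lies antisense to DLX6, rose by 1.85 ± 0.08. Reads of DLX6 and DLX6-AS1 cannot be told apart where the genes overlap, because no strand setting of the counting is given. DLX4 was near the floor, at 0.949 CPM against 0.192 CPM, and its log2 fold change was 2.89 without control replicate 1. All 3 tested DLX genes other than DLX5 were higher, and the list passed the list test (adjusted p = 0.0394), with adjusted p = 0.171 with an estimated correlation. The list lost its call with DESeq2 values (adjusted p = 0.0506), without control replicate 2 (adjusted p = 0.0598) and without control replicate 3 (adjusted p = 0.0522).

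MYCN (ENSG00000134323, chromosome 2, 15940564 to 15947007, plus strand) was 5.45-fold higher with DLX5. Its level was 26.6 ± 0.344 CPM in the DLX5 libraries and 4.89 ± 0.488 CPM in the controls (SD, n = 3), a log2 fold change of 2.45 with a standard error of 0.11 (edgeR, adjusted p = 3.65e-16). MYCNOS overlaps MYCN on the other strand and took 108 counts over all libraries, against 1525 for MYCN. MYC, the more abundant member of the family in these cells, fell from 92.3 ± 6.08 to 68.5 ± 0.587 CPM, and MYCL, named after its values were seen, fell from 9.97 ± 0.635 to 7.53 ± 1.02 CPM. The fall of MYCL did not pass the threshold without DLX5 overexpression replicate 1 (log2 fold change -0.34, adjusted p = 0.0649). The sum of MYC, MYCN and MYCL was 103 ± 1.69 CPM with DLX5 and 107 ± 7.18 CPM in control, and the library values of the groups overlapped. Among the 12 tested MYC family genes and partners 4 rose, 2 fell and 6 did not pass. AURKA, a mitotic kinase known to stabilise the MYCN protein, rose by 0.86 ± 0.08 and MXD4 by 0.25 ± 0.06. The list as a whole did not pass (adjusted p = 0.611).

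**Figure D1:**
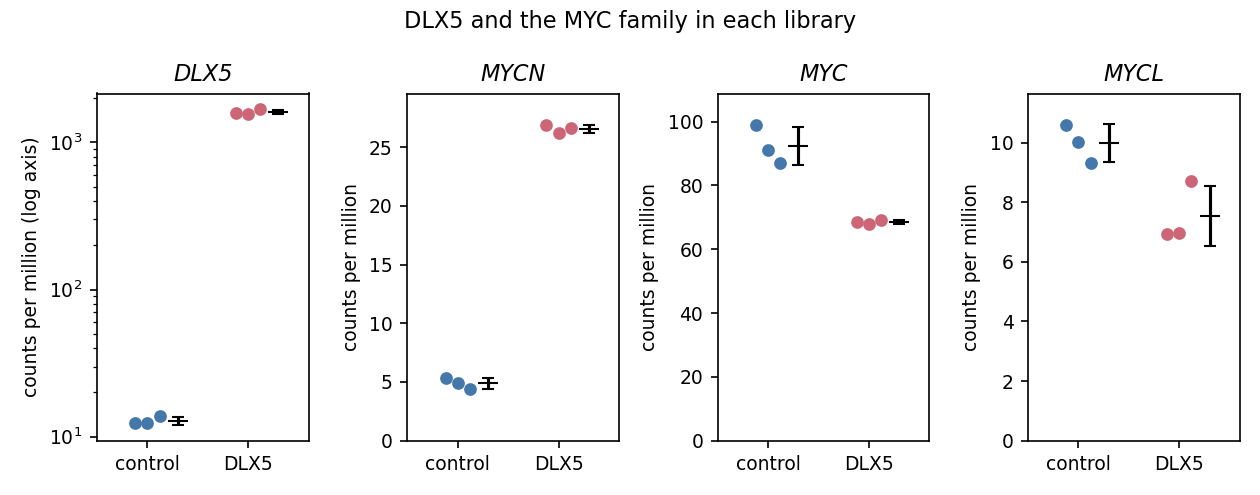
Levels of DLX5, MYCN, MYC and MYCL in CPM for each library (points) by group (control in blue, DLX5 overexpression in red), with the mean and SD in black (n = 3). The axis of DLX5 is logarithmic and the others start at 0; MYCN was at 26.6 CPM with DLX5 and 4.89 CPM in control, while MYC was at 68.5 and 92.3 CPM.

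Genes known as MYC and MYCN targets were mostly lower with DLX5. Of the 36 tested, 32 fell, 1 rose and 3 did not pass, with a median log2 fold change of -0.49 (adjusted p = 1.46e-07; adjusted p = 0.0754 with an estimated correlation). The replication helicase subunit MCM4 fell by 1.34 ± 0.06 and MCM5 fell by 0.84 ± 0.06, the nucleolar protein NOLC1 fell by 0.81 ± 0.06 and the nucleoside diphosphate kinase NME1 fell by 0.88 ± 0.07 (log2 fold change ± SE). The exceptions, named after their values were seen, included the transferrin receptor TFRC, which rose by 0.32 ± 0.06, and ODC1, the first enzyme of polyamine synthesis, at a log2 fold change of 0.01 ± 0.06. Ribosomal protein genes were lower too. Of 35 tested, 32 fell and 0 rose, by a median of -0.35 (adjusted p = 7.89e-05; adjusted p = 0.535 with an estimated correlation). RPL27A fell by 0.49 ± 0.06, RPL7A fell by 0.47 ± 0.06, RPS15 fell by 0.52 ± 0.07 and RPL18 fell by 0.49 ± 0.06. Ribosomal protein genes have many processed pseudogenes, and reads shared with these were not measured. The median of this list was negative under every scaling tried. Adjusted over the list alone, 32 MYC target genes and 33 ribosomal protein genes were lower.

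In all, 10121 of the 17269 genes tested changed with DLX5, 5152 of them higher and 4969 lower (edgeR, Benjamini-Hochberg adjusted p under 0.05). Large changes were mostly rises. At 2-fold or more 1944 genes were higher and 895 lower, and at 8-fold or more 468 were higher and 47 lower. In 62.5% of the tested genes the 3 values of one group lay above all 3 of the other, against 10% by chance. The first principal component held 86.2% of the variance and separated the groups.

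The largest rises among well-expressed genes were in genes that the controls barely held. CYP26A1 (ENSG00000095596, chromosome 10, 93073475 to 93077890, plus strand), the enzyme that degrades retinoic acid, was at 20.8 ± 1.58 CPM with DLX5 and had 0 counts in all 3 controls, which makes it at least 334-fold higher against a floor of 3 counts over the group. FGL2, a secreted fibrinogen-like protein, reached 39.2 ± 2.12 CPM against 1 control count, the homeobox gene HMX2 13.8 ± 0.118 CPM against 1, the serotonin receptor HTR1D 11.4 ± 0.917 CPM against 1, the guanine deaminase GDA 23.3 ± 3.26 CPM against 2, the homeobox gene PITX1 12.2 ± 1.31 CPM against 2, and the adhesion receptor ADGRG6 24.1 ± 0.806 CPM against 3. The ratio of scaled counts was 1884 for FGL2 (95% counting interval 338 to 74451), 661 for HMX2 (118 to 26145), 549 for HTR1D (98.2 to 21729), 558 for GDA (154 to 4610), 293 for PITX1 (80.7 to 2424) and 385 for ADGRG6 (131 to 1871). These intervals cover counting error only. The prostaglandin receptor PTGER4, the fibrillin FBN2, the cytokine IL18, the R-spondin receptor LGR6 and the potassium channel KCNJ15 rose by 8.16 ± 0.24, 7.73 ± 0.23, 7.57 ± 0.31, 7.35 ± 0.18 and 7.34 ± 0.17 (log2 fold change ± SE). In that order they had 5, 8, 5, 12 and 14 counts over the controls. With so few counts these standard errors are smaller than the counting error. Single control libraries weighed on the fitted sizes, though not on the calls. Without control replicate 1 the fitted log2 fold changes were 12.32 for FGL2, 10.54 for HTR1D, 11.62 for ADGRG6, 9.72 for PTGER4 and 11.44 for IL18, without control replicate 2 they were 7.58 for PTGER4, 7.13 for FBN2 and 6.99 for IL18, and without control replicate 3 they were 10.78 for HMX2 and 9.02 for FBN2.

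The largest falls included the growth factor IGF2 (ENSG00000167244, chromosome 11, 2129112 to 2149603, minus strand), which went from 15.8 ± 1.64 CPM in control to 0.141 ± 0.193 CPM with DLX5, a log2 fold change of -6.70 with a standard error of 0.30 that became -8.65 without DLX5 overexpression replicate 1. IGF2 had 7 counts over the DLX5 libraries, so few that its standard error is smaller than the counting error. The gene overlaps INS-IGF2 and an antisense gene. The zinc finger gene INSM2 fell by 4.75 ± 0.25, the kinase gene DCLK3 fell by 4.25 ± 0.17, ODAM fell by 3.99 ± 0.27 and the bone morphogenetic protein BMP7 fell by 3.83 ± 0.14 (log2 fold change ± SE). CHGA, the chromogranin of catecholamine storage granules, fell by 3.76 ± 0.08, from 745 ± 67.0 to 54.9 ± 3.81 CPM, and RGS4, a regulator of G protein signalling, fell by 3.17 ± 0.07, from 532 ± 35.7 to 59.1 ± 4.48 CPM. LINGO4, HSD11B1, ZMAT4 and FAM198B fell too, with log2 fold changes of -3.81 ± 0.14, -3.34 ± 0.20, -3.28 ± 0.22 and -3.17 ± 0.17. INSM2, DCLK3, ODAM, LINGO4, HSD11B1 and ZMAT4 had 23, 57, 29, 96, 47 and 40 counts over the DLX5 libraries. Their standard errors are smaller than the counting error too. The remaining gene of the 12, BOLA2B, is uncertain. It has a near-identical copy, its log2 fold change of -4.12 was -1.39 without control replicate 3, and it did not pass on log2(FPKM + 1) values (adjusted p = 0.0815).

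**Figure D2:**
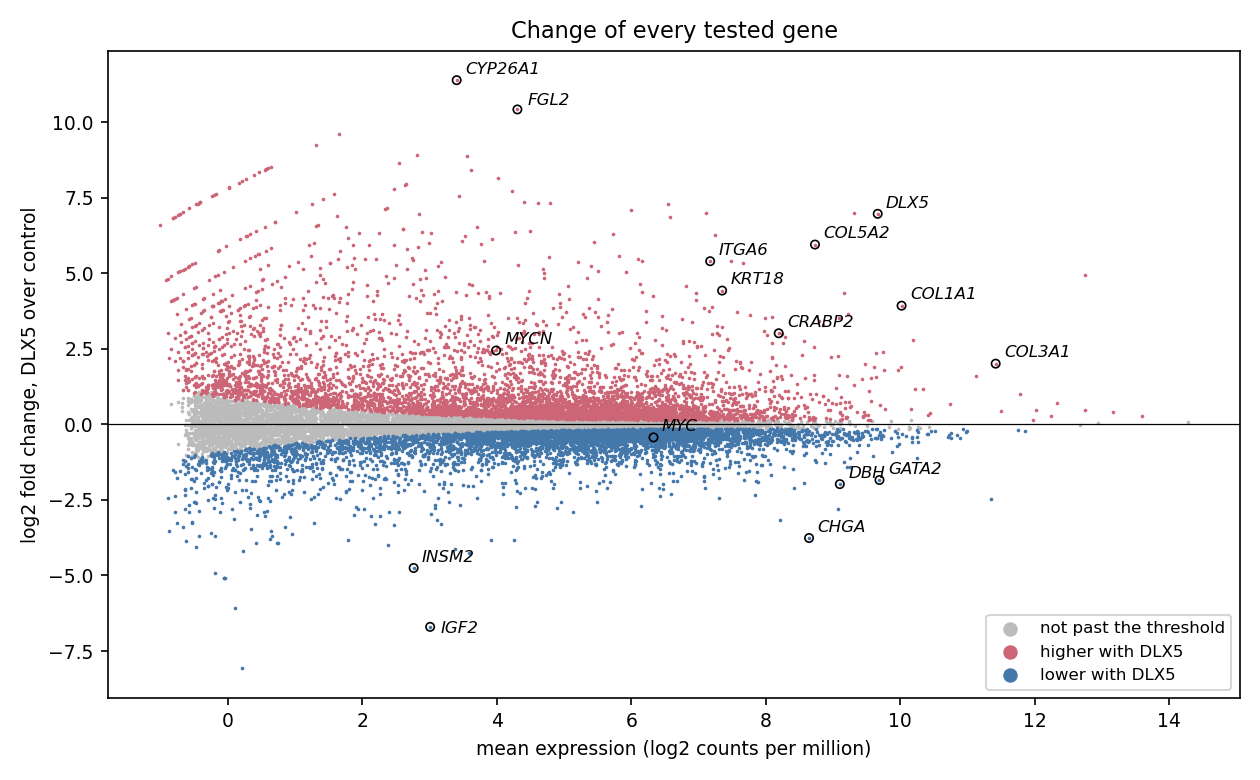
Log2 fold change of each of the 17269 tested genes (DLX5 overexpression over control) against mean expression in log2 CPM, with genes past the threshold in red (higher) and blue (lower) and others in grey. Circled genes are named in the text; fitted values at the top left rest on few or no control counts, and DLX5 stands at 6.97.

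Genes of the sympathetic neuron programme fell together. Of 23 tested adrenergic neuroblastoma regulators 19 fell, 2 rose and 2 did not pass, with a median of -1.26 (adjusted p = 1.39e-18; adjusted p = 0.0754 with an estimated correlation). The transcription factors HAND1, GATA2, GATA3 and TFAP2B fell, with log2 fold changes of -2.09 ± 0.07, -1.84 ± 0.06, -1.68 ± 0.06 and -1.61 ± 0.06 (± SE). GATA2 went from 1292 ± 77.6 to 361 ± 12.4 CPM. The genes of catecholamine synthesis and storage fell by a median of -1.88, with 11 of 13 lower and 0 higher (adjusted p = 4.57e-18, and 0.0119 as adjusted p with an estimated correlation). DBH, which makes noradrenaline, went from 876 ± 32.0 to 222 ± 8.78 CPM, DDC fell by 2.38 ± 0.07 and CYB561 fell by 2.33 ± 0.06. TH, the rate-limiting enzyme of the pathway and named after its values were seen, had 80 counts in control and 2 with DLX5, a ratio of 0.0247 (95% counting interval 0.00295 to 0.0923). Neuronal differentiation genes fell by a median of -1.15, with 22 of 27 lower and 0 higher (adjusted p = 7.34e-15). The neurofilament gene NEFM fell by 1.65 ± 0.07, the synaptic gene SNAP25 fell by 1.63 ± 0.07, STMN2 fell by 1.41 ± 0.06 and INA fell by 1.32 ± 0.06.

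Matrix and mesenchymal genes moved the other way. Of 34 tested extracellular matrix and integrin genes 32 rose and 1 fell, with a median of 1.42. The list test gave adjusted p = 9.87e-41, and 0.0119 as adjusted p with an estimated correlation. The fibrillar collagen COL5A2 went from 13.5 ± 1.5 to 836 ± 27.8 CPM, COL1A1 from 128 ± 8.03 to 1947 ± 52.7 CPM, the laminin receptor ITGA6 from 6.65 ± 0.620 to 282 ± 25.1 CPM and the collagen cross-linking enzyme LOX from 20.8 ± 3 to 219 ± 9.36 CPM. The gelatinase MMP2 was the member that fell, by 0.42 ± 0.06, and is named after its values were seen. Of 29 tested regulators of the mesenchymal neuroblastoma state 25 rose, 2 fell and 2 did not pass, with a median of 0.77 (adjusted p = 2.05e-10). CD44 rose by 2.30 ± 0.07, and the Hippo pathway coactivators WWTR1 and YAP1 by 2.30 ± 0.09 and 2.15 ± 0.09. Among 15 genes of the epithelial to mesenchymal list 11 rose and 1 fell (median 0.75, adjusted p = 7.67e-08). The members that rose were of both kinds. CDH11 rose by 2.53 ± 0.06 and VIM by 1.09 ± 0.06, and so did the epithelial keratins KRT18 and KRT8, by 4.43 ± 0.08 and 4.35 ± 0.15, while SNAI1, named after its values were seen, fell by 2.0 ± 0.13. KRT8 and the more abundant KRT18 have many pseudogenes and overlap in the annotation.

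Osteogenic and chondrogenic genes, which DLX5 is known to regulate in the skeleton, rose by a median of 1.99, with 9 of 13 higher and 2 lower (adjusted p = 3.04e-07). Of the 23 genes in the list only 13 could be tested, and 8 of these were at 1 CPM or more in control. COL1A1, which is also in the matrix list, rose by 3.93 ± 0.07, the homeobox gene MSX2 by 1.99 ± 0.08 and SPARC by 1.0 ± 0.06. RUNX2, the osteoblast regulator, fell by 1.53 ± 0.28 at a low level of 2.87 ± 0.445 CPM in control. It was named after its values were seen and overlaps the more abundant SUPT3H.

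Markers of other cell types were measured beside these groups. The controls themselves held the fibroblast markers, so these do not by themselves mark foreign cells. Fibroblast markers rose with the matrix genes, 8 of 9 tested higher and 0 lower (median 1.15, adjusted p = 4.62e-08), and their summed level went from 1511 to 5181 CPM. All 9 were at 1 CPM or more in control, and 3 of them are also in other lists. COL3A1 went from 1089 ± 17 to 4383 ± 77.3 CPM, LUM from 6.82 ± 0.290 to 63.4 ± 1.14 CPM, FAP from 6.36 ± 0.421 to 36.2 ± 1.38 CPM and TAGLN from 114 ± 3.42 to 274 ± 4.03 CPM. Of 8 epithelial markers, 4 of them also in the epithelial to mesenchymal list, 5 rose and 1 fell (median 3.59, adjusted p = 3.04e-07; adjusted p = 0.0865 with an estimated correlation). ELF3 rose by 3.65 ± 0.18 and CLDN7, which overlaps the more abundant ELP5, by 3.54 ± 0.26, whereas KRT19, named after its values were seen, fell by 3.68 ± 0.41 from 2.76 ± 0.747 CPM. Schwann-like and glial markers went both ways, with 3 of 7 higher and 2 lower (adjusted p = 0.917). MBP rose by 2.68 ± 0.22 and ERBB3 by 2.32 ± 0.24, PMP22 fell by 0.98 ± 0.08 and S100B fell by 2.75 ± 0.40. Of 4 endothelial and blood markers only PECAM1 rose (list adjusted p = 0.662), to 0.842 ± 0.132 CPM against 2 control counts, a ratio of 20.3 with a 95% counting interval of 5.27 to 173, and none reached 1 CPM in control. TIE1, VWF and CD14 had log2 fold changes of 0.81 ± 0.43, 0.58 ± 0.45 and 0.39 ± 0.41.

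**Figure D3:**
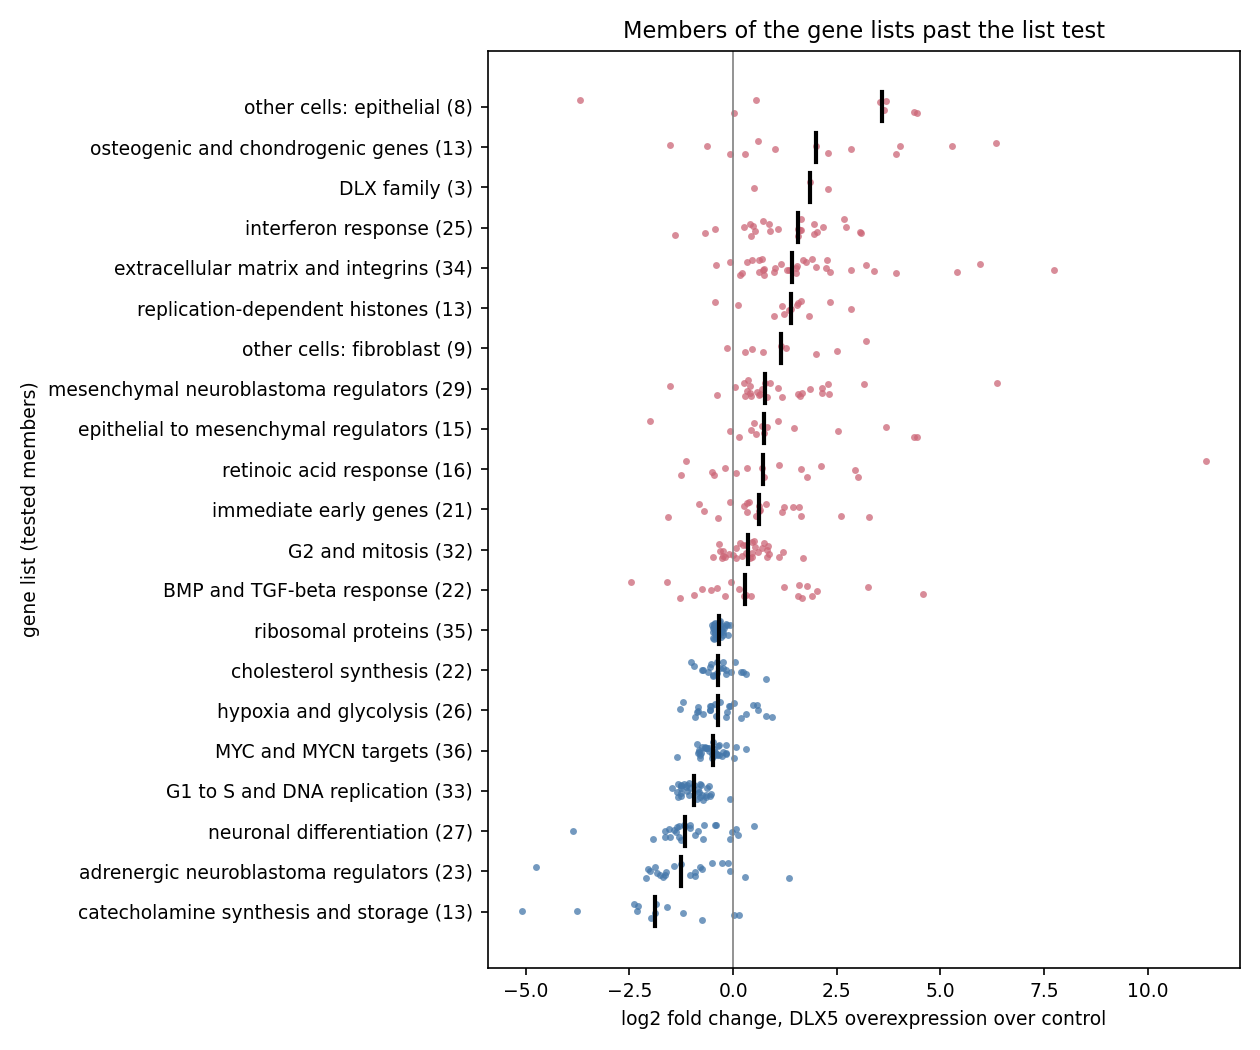
Log2 fold change of each tested member (points) of the 21 gene lists past the list test, DLX5 overexpression over control, with each list's median as a black bar and its number of tested members in brackets. Lists with a median above 0 are in red and those below 0 in blue; catecholamine genes had a median of -1.88 and matrix genes of 1.42.

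Cell cycle genes split by phase. Of 33 tested genes of the G1 to S transition and DNA replication 32 fell and 0 rose, with a median of -0.95 (adjusted p = 9.72e-20, and 0.025 as adjusted p with an estimated correlation). The ribonucleotide reductase subunit RRM2 fell by 1.47 ± 0.07, MCM4 fell by 1.34 ± 0.06, the flap endonuclease FEN1 fell by 1.27 ± 0.06, PCNA fell by 1.25 ± 0.06 and CCND1, named after its values were seen, fell by 1.13 ± 0.06 (log2 fold change ± SE). FEN1 overlaps FADS2. Of 32 genes of G2 and mitosis 21 rose and 7 fell, with a median of 0.36 (adjusted p = 0.025; adjusted p = 0.453 with an estimated correlation, and 0.051 as adjusted p among protein-coding genes only). CDC20 rose by 1.20 ± 0.06, the centromere proteins CENPE and CENPF by 1.68 ± 0.11 and 1.1 ± 0.08, KIF20A by 0.85 ± 0.06 and MKI67, named after its values were seen, by 0.53 ± 0.06. Replication-dependent histone genes, whose messages mostly lack a poly(A) tail, rose at low levels, 11 of 13 higher and 0 lower (median 1.40, adjusted p = 0.0394; adjusted p = 0.271 with an estimated correlation). This call was lost with DESeq2 values (adjusted p = 0.0736), with no filter on low counts (adjusted p = 0.0558) and among protein-coding genes only (adjusted p = 0.0617). HIST1H2AC went from 2.45 ± 0.367 to 12.4 ± 1.44 CPM, and HIST1H2BD, HIST2H2BE and HIST1H2AG rose by 1.57 ± 0.16, 1.40 ± 0.16 and 1.84 ± 0.24. Histone genes are a family of near-identical copies, and of the 33 in the list only 13 could be tested. Of 25 tested p53 targets and cell cycle inhibitors 16 rose and 5 fell (adjusted p = 0.148), with FAS up by 3.44 ± 0.12, RRM2B by 0.79 ± 0.08, BTG2 by 0.58 ± 0.08 and DDB2 by 0.53 ± 0.07. FAS overlaps ACTA2. The list passed with limma-voom (adjusted p = 0.0326), with no filter (adjusted p = 0.0209) and on log2(FPKM + 1) and log2(FPKM + 0.1) values (adjusted p = 0.0376 and 0.0483).

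Signalling lists held large changes in single members. Of 25 interferon response genes 21 rose and 2 fell, with a median of 1.55 (adjusted p = 2.98e-07, and 0.0193 as adjusted p with an estimated correlation). HLA-C rose by 2.03 ± 0.06, HLA-B by 2.71 ± 0.09, B2M by 1.63 ± 0.06 and the immunoproteasome subunit PSMB9 by 3.07 ± 0.13. HLA-B and the more abundant HLA-C are close paralogs that overlap in the annotation, and PSMB9 overlaps the more abundant TAP1. Of 16 retinoic acid response genes 10 rose and 5 fell (median 0.72, adjusted p = 0.00333; adjusted p = 0.089 with an estimated correlation). The median does not move with CYP26A1 at its bound. CRABP2, which carries retinoic acid to its receptors, rose by 3.02 ± 0.06 and TGM2 by 1.64 ± 0.06, and the receptor tyrosine kinase RET fell by 1.25 ± 0.06. Of 22 BMP and TGF-beta response genes 12 rose and 8 fell (median 0.28, adjusted p = 0.00116; adjusted p = 0.112 with an estimated correlation). INHBA rose by 3.25 ± 0.08, CTGF by 4.58 ± 0.11, CYR61 by 1.78 ± 0.06 and the BMP antagonist GREM1 by 1.6 ± 0.06. The call of this list was lost with limma-voom (adjusted p = 0.071) and on log2(FPKM + 1) and log2(FPKM + 0.1) values (adjusted p = 0.135 and 0.17). Immediate early genes rose in 15 of 21 and fell in 4 (median 0.61, adjusted p = 0.0247; adjusted p = 0.453 with an estimated correlation), with EGR2 up by 3.27 ± 0.14, DUSP1 by 1.58 ± 0.07, IER3 by 1.44 ± 0.10 and JUN by 1.18 ± 0.07.

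The WNT and NOTCH lists did not pass. Of 21 WNT genes 10 rose and 9 fell (adjusted p = 0.155), with the antagonists DKK1 and DKK3 up by 1.96 ± 0.07 and 1.40 ± 0.06, WNT5A by 1.54 ± 0.09 and TCF7L2 by 1.63 ± 0.09. Of 18 NOTCH genes 8 rose and 8 fell (adjusted p = 0.24), and the list's median of -0.09 differed in sign from its mean of 0.37 and from its test. The ligand JAG1 rose by 3.11 ± 0.07, DTX4 by 4.14 ± 0.11 and NOTCH3 by 1.56 ± 0.07, while LFNG fell by 1.87 ± 0.08. GABAergic neuron genes, a class that DLX factors specify in the forebrain, were mostly too low to test. Of the 8 tested 4 rose and 3 fell (adjusted p = 0.971), with MAF up by 6.52 ± 0.20, RELN up by 1.99 ± 0.08, VIP down (-1.89 ± 0.07) and SIX3 down (-1.76 ± 0.07), and the positive median of 0.15 and mean of 0.89 differed in sign from the test. MAF had 13 counts over the controls, so few that its standard error is smaller than the counting error. Axon guidance genes rose in 14 of 25 and fell in 9 (adjusted p = 0.0886), with ROBO1 up by 2.19 ± 0.07, SEMA3A by 2.44 ± 0.11, ROBO2 by 1.66 ± 0.08 and UNC5B down (-1.17 ± 0.06). This list passed with no filter on low counts (adjusted p = 0.01), without DLX5 overexpression replicate 3 (adjusted p = 0.0449) and without control replicate 3 (adjusted p = 0.0495). Of 13 HOX genes 3 rose and 6 fell (adjusted p = 0.24), with HOXD8, HOXD9 and HOXD10 at log2 fold changes of -0.70 ± 0.07, -0.68 ± 0.07 and -0.54 ± 0.08 and HOXC8 up by 1.57 ± 0.32 from 0.691 ± 0.137 CPM. HOXC8, with 133 counts over all libraries, overlaps HOXC6, with 1202, on the same strand.

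Among the metabolic lists, hypoxia and glycolysis genes fell in 15 of 26 and rose in 7 (median -0.37, adjusted p = 0.0089; adjusted p = 0.0865 with an estimated correlation). VEGFA, EGLN3 and ENO2 fell (log2 fold changes -1.21 ± 0.07, -1.27 ± 0.08 and -0.88 ± 0.06), and P4HA1, which hydroxylates collagen, rose by 0.93 ± 0.07. Cholesterol synthesis genes fell in 15 of 22 and rose in 3 (median -0.36, adjusted p = 0.025; adjusted p = 0.113 with an estimated correlation). MVK, which overlaps the more abundant MMAB, and EBP fell (log2 fold changes -1.0 ± 0.10 and -0.74 ± 0.08). Nuclear genes of oxidative phosphorylation missed the threshold (12 of 27 lower and 0 higher, median -0.15, adjusted p = 0.0503) and passed with 8 of the alternatives besides fry, among them without DLX5 overexpression replicate 3 (adjusted p = 0.0278) and without control replicate 3 (adjusted p = 0.0159). ATP5MC1 fell by 0.71 ± 0.07, UQCRH fell by 0.43 ± 0.06, ATP5F1B fell by 0.34 ± 0.06 and NDUFB9 fell by 0.43 ± 0.07. Of the 13 mitochondrially encoded genes 8 rose and 2 fell (median 0.36, adjusted p = 0.269), with MT-CYB up by 0.49 ± 0.07, MT-CO2 by 0.47 ± 0.07, MT-ND6 by 0.52 ± 0.07 and MT-ND5 by 0.43 ± 0.07. That list passed with limma-voom (adjusted p = 0.035) and with no filter (adjusted p = 0.0382), and MT-CO2 did not pass on log2(FPKM + 1) or log2(FPKM + 0.1) values (adjusted p = 0.106 and 0.132). Of 24 genes of the unfolded protein and integrated stress response 13 rose and 4 fell (adjusted p = 0.279), with PDIA4 up by 1.21 ± 0.06, HSP90B1 by 0.78 ± 0.06, ERN1 by 0.93 ± 0.08 and PHGDH down (-0.53 ± 0.06). Of 25 apoptosis genes 12 rose and 4 fell (adjusted p = 0.332), with CASP8 up by 2.42 ± 0.14, CFLAR by 1.45 ± 0.08, BIRC3 by 1.3 ± 0.11 and CYCS down (-0.64 ± 0.06).

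Across the 34 lists 21 passed, 13 upwards and 8 downwards (camera with a preset correlation of 0.01, adjusted over the 34 lists). Adjusted over the list alone, the numbers of members that rose or fell differed from those above in 7 lists, by 1 gene each. With an estimated correlation 9 passed, and these were the mesenchymal regulators, the epithelial to mesenchymal list, the matrix and integrin genes, the osteogenic genes, the interferon response and the fibroblast markers, all upwards, and the catecholamine, neuronal differentiation and G1 to S lists, all downwards. The adjusted p-values of these 9 lists with an estimated correlation ran from 0.0119 to 0.0292, far weaker than with the preset correlation. Some of these lists share members with other lists: 13 of 29 mesenchymal, 7 of 15 epithelial to mesenchymal, 7 of 34 matrix and 5 of 13 osteogenic members tested are also in another of the 34.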

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

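Library totals with no scaling factors and the test against 1.5-fold were chosen after the data were seen; all other alternatives were planned. DLX5 and MYCN passed in the same direction under all 17 alternatives, at log2 fold changes from 6.79 to 7.02 and from 1.96 to 2.51. The count of 10121 changed genes stayed within 1.5 times under the other scalings, filters and tools. A minimum change of 2-fold left 2839 genes (1944 higher, 895 lower), and a test against 1.5-fold left 3284 (2158 higher, 1126 lower), fewer because small changes do not count. With one library left out 9277 to 9841 genes changed (4837 to 5061 higher, 4440 to 4780 lower), and of the 9347 called by DESeq2 9338 were among the 10121. The share of higher calls was 50.9%, 47.5% with upper-quartile factors and 44.2% with library totals only, where the median of all genes lay at -0.07. The count of 21 lists became 9 with an estimated correlation, which allows for members that move together, and 32 with fry, which does not compare a list with other genes. It was 20 to 23 with one library left out. No gene list, and no named gene, reversed. Of the named genes, DDX1 passed with library totals only (-0.17) and without control replicate 1 (-0.17).

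The replicate numbers did not clearly pair the libraries, and 3 libraries per group are too few to exclude pairing. Deviations of same-numbered libraries correlated at 0.007, 0.094 and -0.040 across genes, and only number 2 correlated best with itself. With the replicate number as a block 10224 genes (5208 higher, 5016 lower) and 21 lists passed, DLX5 stood at 6.97 and MYCN at 2.45, and no call of a list or a named gene changed. Simulated changes of 1.25-fold were recovered in 30.6% of genes. Small changes can be missed, but at a rate this does not measure, because far fewer genes were changed in the simulation than called here.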

Other observations

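Of the tests below, those of the spread of adrenergic genes, of the chromosome 12 segment, of windows of abundant genes, of an unlike DLX5 line and of fewer dividing cells were chosen only after the result was seen.

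Among 15 families of transcription factors given in the annotation of the files, 23 of 43 tested bZIP genes were higher and 6 lower (median 0.33, camera adjusted p = 0.00964; adjusted p = 0.278 with an estimated correlation), with MAF, given above, rising most. GATA-type zinc finger genes passed downwards with 5 of 10 lower and 1 higher (adjusted p = 0.00964; adjusted p = 0.278 with an estimated correlation). The only members lower by 2-fold or more were GATA2 and GATA3, also given above. The 77 tested homeobox genes other than DLX5 went both ways, with 32 higher and 27 lower (adjusted p = 0.601). HMX3, the homologue of HMX2 and named after its values were seen, had 0 control counts and was at least 97.0-fold higher.

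Some of the most abundant transcripts changed as well, named here after their values were seen. ELN, the gene of the elastic fibre protein elastin (ENSG00000049540, chromosome 7, 74027789 to 74069907, plus strand), went from 433 ± 22.7 to 13297 ± 738 CPM (SD, n = 3). ABI3BP, a matrix protein gene, went from 9.80 ± 0.968 to 1259 ± 28.2 CPM, a log2 fold change of 7.0 ± 0.08 (SE). The pericyte-associated gene RGS5 fell by 2.48 ± 0.07 (log2 fold change ± SE), from 4439 ± 273 to 796 ± 51.6 CPM.

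For the counts of calls, 10 splits of the 6 libraries into 3 and 3 exist, too few for a share under 0.05. The real split gave 10121 genes and 21 lists, and in each case it was 1 split of the 10 with as many. The other 9 splits gave at most 0 genes with edgeR (64 to 294 at an unadjusted p under 0.05) and at most 0 with limma-voom, and 13 to 16 lists. Each of those splits sets 2 libraries of one group against 1 of the other on each side. Part of the DLX5 difference stays between the sides, and the rest widens the spread within them. The 64 to 294 genes are fewer than that threshold would give by chance. Finding 0 genes was therefore built into these splits and says nothing about chance. The list test with the preset correlation still passed 13 to 16 lists there. Those calls may hold part of the DLX5 difference, so they do not show how many of the 21 arise by chance.

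The rise of MYCN came with a fall of the genes known as MYC and MYCN targets, a list that lost its call with an estimated correlation (adjusted p = 0.0754). Extra copies of the MYCN region are argued against by 9 tested genes within 2 Mb, whose median log2 fold change was 0.31 (SD 0.86) against 2.45 for MYCN. They ran from -0.38 to 1.92, and 3 of them were above 1.5. DDX1 and NBAS, the nearest of them and named after their values were seen, were at -0.11 ± 0.07 and 0.29 ± 0.07. Both lie at lower coordinates than MYCN. FAM49A, the nearest on the other side, was at 0.90 ± 0.15. The 3 genes above 1.5 lie on that side too, as do GEN1 at -0.38 and SMC6 at 0.31. Extra copies of MYCN without these neighbours were not tested. GC content and gene length do not account for the targets, whose median was -0.46 once the trend was removed. A larger fall of MYC and MYCL than the rise of MYCN stays open, because the summed CPM of the family was 0.957 times the control level and the libraries overlapped. A candidate explanation is that MYC-driven genes follow the summed family level or the cell cycle more than MYCN alone. The summed RNA, at 0.957 times control, changed little beside the targets' median of -0.49. Targets that followed this sum in proportion would not fall so far. MYC alone was at a log2 fold change of -0.43 ± 0.07 (SE), near the targets' median, so targets that followed MYC alone stay open. Counts of RNA cannot decide the rest, since protein was not measured.

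The fall of adrenergic genes beside the rise of mesenchymal genes could come from a shift in cell state, from a mixture of cells or from a difference between the lines. The adrenergic list lost its call with an estimated correlation (adjusted p = 0.0754). Dilution of unchanged cells by cells that lack adrenergic transcripts would lower all of these genes by one factor, but the log2 fold changes of 31 genes had an interquartile range of 1.18 with a median standard error of 0.07, from -4.75 for INSM2 to 0.29 for SOX11, and GC content and length left the lists 2.04 apart. Gained or lost chromosome segments remain open. A median beyond 0.4 in a window of 100 neighbouring genes was set in advance as their sign. A single shuffle of the genes gave a largest median of 0.21 in size. Shuffling also parts neighbours that change together for other reasons, so this is no bound for unchanged copy number. The highest real window, on chromosome 12 (12875499 to 32896840), was at 0.47. The 33 abundant genes of that window had a median of 0.053 but an SD of 1.74, too wide to decide, and 0 of the 52 tested adrenergic and mesenchymal regulators lie in it. Over 4566 windows of 100 abundant genes, which cover longer stretches, the largest median in size was -0.21, which goes against long segments and leaves shorter ones open. A DLX5 line that differed from the control line apart from DLX5 cannot be told apart from an effect of DLX5, since 0 labels name a clone, and mixing with cells that keep some adrenergic transcripts was not tested.

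The G1 to S and replication genes fell, while 21 of 32 mitotic and 11 of 13 histone genes rose. Both of the lists that rose lost their call with an estimated correlation (adjusted p = 0.453 and 0.271) and among protein-coding genes only (adjusted p = 0.051 and 0.0617). Fewer dividing cells as the whole cause would lower both phases, yet only 7 of 32 G2 and mitosis genes fell against 32 of 33 in the G1 to S list, with medians of 0.36 (SD 0.51) and -0.95. GC content and length left the G1 to S median at -0.92. For the histone genes, more RNA without a poly(A) tail in the DLX5 libraries stays open, because the 11 tested small nuclear and nucleolar RNAs had a median of -0.15 but a median control level of only 0.764 CPM.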
